A study of Mus musculus with 2 samples.

How the data were processed

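Trimethylation of histone H3 at lysine 9 (H3K9me3), a mark of silenced chromatin, was measured by ChIP-seq in lung of mouse embryos at day 15.5 (strain B6NCrl). Per the labels, the 2 biological replicates of the single group were pools of both sexes, replicate 1 from 78 embryos and replicate 2 from 62, with library fragments of 300 to 500 bp. The 4 deposited files are peak lists in mm10 coordinates. Per the file headers and the texts deposited with them, the authors called peaks on each replicate's alignments with a control, called a pooled list on the alignments of both replicates with both controls, and derived from these a replicated list. Every one of the 4560 replicated peaks was also in the pooled list, with identical values. The peak caller, its version, the aligner and the rule that defined a replicated peak are not given in the sources used here. Since the pooled and replicated lists draw on both samples, they hold no spread between replicates.

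In each list the authors deposited a score per peak, a fold enrichment (a ratio of ChIP over control) and the −log10 of the peak's p-value and q-value. These are the authors' own values for a peak and were used here only to describe, rank or filter peaks within one list. The lists begin at a −log10 p of about 2.00, which admits peaks that do not pass a q of 0.05. The lists give no read counts, so sequencing depth is unknown, and no interval that needs it was computed. Narrow peaks were called for a mark that covers broad domains, so 1 domain can be split into many peaks, and how reads from repeated sequence were treated is not stated.

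Positions were compared with GRCm38, the same build as mm10, and GENCODE release M21. Peaks on unplaced scaffolds entered only counts, and all tests used the 21 assembled chromosomes (2648 Mb without assembly gaps). Peaks of the replicate lists were called shared when they overlapped by at least 1 bp. The null for overlap, gene annotation, masked sequence, GC content and gene lists came from 10000 rotations of all peaks of a chromosome by 1 random shift along that chromosome, with assembly gaps removed. This keeps peak width and the clustering of both peaks and genes. These p-values describe positions along the genome in these lists, not the spread between embryos. The permutation p is two-sided, and 0.0002 is the smallest that 10000 rotations can give (0.002 for the 1000 rotations used for alternatives). Gene annotation was assigned to peak midpoints in the order within 1 kb of a protein-coding transcription start site (TSS), exon, intron, between genes. Masked sequence is the lower-case part of the reference (36.4% of the ungapped genome). The masking program is not given, and repeat families were not analysed here. For chromosomes, replicated peaks within 10 kb were merged into domains, and domain counts were tested with an exact two-sided binomial test against the chromosome's share of ungapped sequence, with Benjamini-Hochberg adjustment over 21 chromosomes.

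Gene lists were fixed before the data were examined. They comprised 19 lists: rule-based gene families (zinc finger genes with at least 2 other zinc finger genes within 250 kb, called clustered, and those with none, called isolated; olfactory and vomeronasal receptors; clustered protocadherins; Hox genes; Rhox, Magea and Xlr genes; keratin-associated, defensin and Skint genes; cytochrome P450, UGT and serpin genes), imprinted and germ line genes, markers of lung epithelium, lung mesenchyme, endothelium, blood, liver, neurons and striated muscle, and housekeeping genes. Zinc finger genes were taken by symbol throughout (Zfp, Zscan, Zkscan, Zik or Znf followed by a digit), so any with other symbols were not counted. The P450, UGT and serpin list and the liver list shared 3 genes. One listed symbol was not found in the annotation. For symbols that occur more than once in it, the longest span was kept (27 duplicates dropped). A gene counted as having a peak when its annotated span, from start to end, shared at least 1 bp with a replicated peak, and p was adjusted by Benjamini-Hochberg over the 19 lists. Where spans overlap, 1 peak counts for several genes. The rotations keep this overlap. The difference between clustered and isolated zinc finger genes was tested with the same rotations.

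Named genes were also chosen by a rule set in advance: the 15 protein-coding genes whose spans hold the replicated peaks of highest fold that were also found in both replicate lists, the 10 genes with the most bases under replicated peaks, up to 4 members per list by the same measure, and the 5 windows of 1 Mb with the most bases under peaks. Where several gene spans hold the same peak of highest fold, only the first gene by start was taken. Nkx2-1, Sftpc, Fgf10 and Tbx4 were always reported. Genes outside this rule that are named were chosen after their values were seen.

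Alternatives comprised a −log10 q of at least 5, the pooled list, each replicate's list alone, other overlap rules, merging distances and promoter widths, gene spans extended by 5 kb or limited to 1 kb around the TSS, genes matched on length, shuffling with bedtools, and chromosomes X and Y left out. Matching on length drew each gene singly. It did not keep the clustering of genes or the sharing of peaks between them, so its p can be too small for arrays. One more alternative, replicated peaks found in both replicate lists, was added after seeing the data. The tests were tested on simulated data. With no effect, 3% of 100 simulated lists of 200 random genes and 4% of lists of 200 neighbouring genes had a p under 0.05 in the gene list test. Here 200 rotations were used, and the simulated peaks lay in small clusters placed at random. These rates therefore do not show how often the test errs for shorter lists or for arrays as dense as the real ones. Lists of 200 genes seeded at 2-fold, 4-fold and 8-fold enrichment returned mean folds of 2.02, 3.97 and 7.72, and were detected in 80%, 100% and 100% of 20 simulated sets each. Peaks were added until each list reached its seeded fold, so the returned folds check only the counting. For replicate overlap, a seeded share of 10% was returned as 10.6%, of which random overlap gave 0.750%. The seeded peaks were copied between the lists, so this too checks only the counting. For chromosomes, a doubled density on chromosome 7 (2-fold) was detected in 100% of 100 simulated sets, and 3% of sets without an effect had any call. These sets drew domains independently, so they do not show how often the test errs where domains cluster. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, bedtools 2.31.1 and BLAST+ 2.17.0.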

Results

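H3K9me3 was profiled by ChIP-seq in embryonic day 15.5 mouse lung, in 2 biological replicates made from pools of 78 and 62 embryos of both sexes. The replicate 1 list held 31117 peaks with a median width of 202 bp, and the replicate 2 list 21116 peaks with a median width of 200 bp. The pooled list held 27479 peaks and the replicated list 4560. Replicated peaks had a median width of 379 bp (interquartile range 294 to 534 bp), covered 2.20 Mb, and had a median fold enrichment over control of 3.21, as given by the authors, with a maximum of 8.48. A q of at most 0.05 was reached by 30.9% of replicate 1 peaks, 8.79% of replicate 2 peaks and 88.9% of replicated peaks. Read depth is unknown, since the lists carry no counts.

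The first comparison asked how far the replicates marked the same sites. On the assembled chromosomes, 3192 of 30782 replicate 1 peaks (10.4%) overlapped a replicate 2 peak, and 3266 of 20838 replicate 2 peaks (15.7%) overlapped a replicate 1 peak. These shares were 24.9-fold and 25.7-fold over the means of 0.416% and 0.610% under rotation of the peaks along their chromosomes (two-sided permutation p = 0.0002 for both, the smallest that 10000 rotations can give). Sharing was concentrated among the most significant peaks. Of the 100 most significant peaks, 87% of replicate 1 and 93% of replicate 2 were shared, against 25.8% and 29.6% of the 5000 most significant. Among peaks with a q above 0.05 the shares were 6.92% and 13.1%. Requiring an overlap of at least 50% of both peaks left 5.07% and 7.49% shared. With only peaks of −log10 q of at least 5 kept in both lists, 14.4% of 354 replicate 1 peaks and 74.1% of 81 replicate 2 peaks were shared. The replicate 1 share is limited here by the 81 replicate 2 peaks that passed this cut. Against the full list of the other replicate, 74.6% of the 354 and 95.1% of the 81 peaks were shared.

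**Figure D1:**
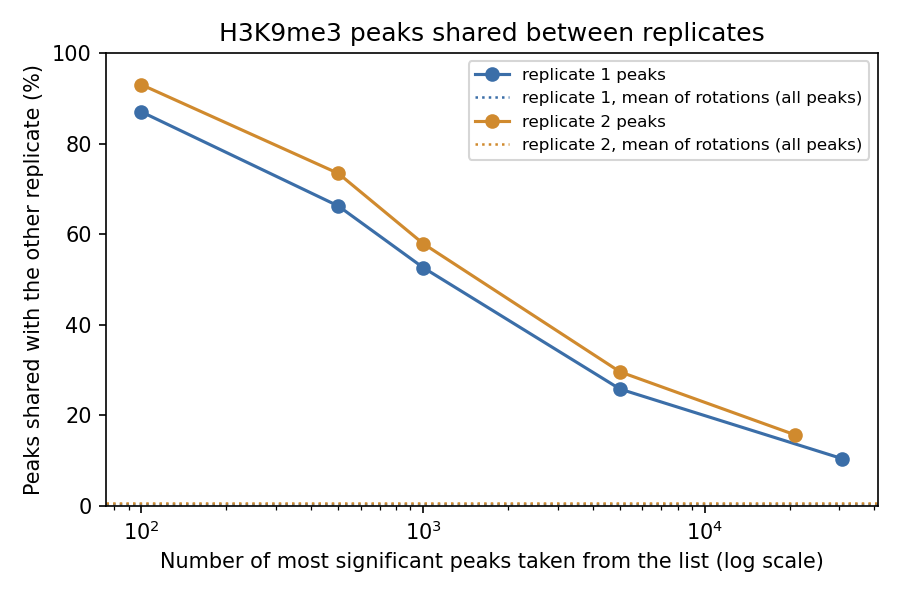
Percentage of H3K9me3 peaks of each replicate that overlap a peak of the other replicate by at least 1 bp, for the 100, 500, 1000 and 5000 most significant peaks and for all peaks on assembled chromosomes (horizontal axis, log scale). Sharing falls from 87% and 93% to 10.4% and 15.7%, above the dotted lines at the bottom, which are the means of rotations for all peaks (0.416% and 0.610%).

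The replicated list held 16.6% of the pooled peaks. Of its 4560 peaks, 3223 (70.7%) overlapped a peak in both replicate lists, 969 a peak of replicate 1 only, 334 a peak of replicate 2 only, and 34 neither. Replicated peaks were wider than the other pooled peaks (median 379 against 210 bp) and had a higher median fold (3.21 against 2.70). A stricter rule, coverage of at least 50% of the peak by both replicate lists, kept 2138 pooled peaks, and all 2138 were in the replicated list. On assembled chromosomes the replicated peaks covered 0.0774% of ungapped sequence. Of the 1319 windows of 1 Mb that held any replicated peak, 98 held 50% of the peak bases.

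The 5 windows of 1 Mb with the most peak bases held several arrays of duplicated genes. The window at chromosome 18: 37000001 to 38000000 (mm10) held 81 replicated peaks over 55115 bp and covers the clustered protocadherins, cell-surface proteins of neurons encoded in tandem. At chromosome 4: 147000001 to 148000000, 95 peaks covered 52684 bp of a window with 9 zinc finger genes, and the neighbouring window from 146000001 to 147000000 had 62 peaks over 34448 bp and 6 zinc finger genes. Zinc finger genes of such arrays encode DNA-binding proteins, many of them repressors of retroviral sequence. The window at chromosome 1: 88000001 to 89000000 held 50 peaks over 39662 bp, with the Ugt1a array of glucuronosyltransferases. The window at chromosome 10: 82000001 to 83000000 held 57 peaks over 34837 bp, with Zfp873 and AU041133. In the order given, the replicated peaks of these windows that overlapped the replicate 1 list numbered 75, 92, 62, 49 and 57, and those that overlapped the replicate 2 list 70, 80, 51, 38 and 46.

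**Figure D2:**
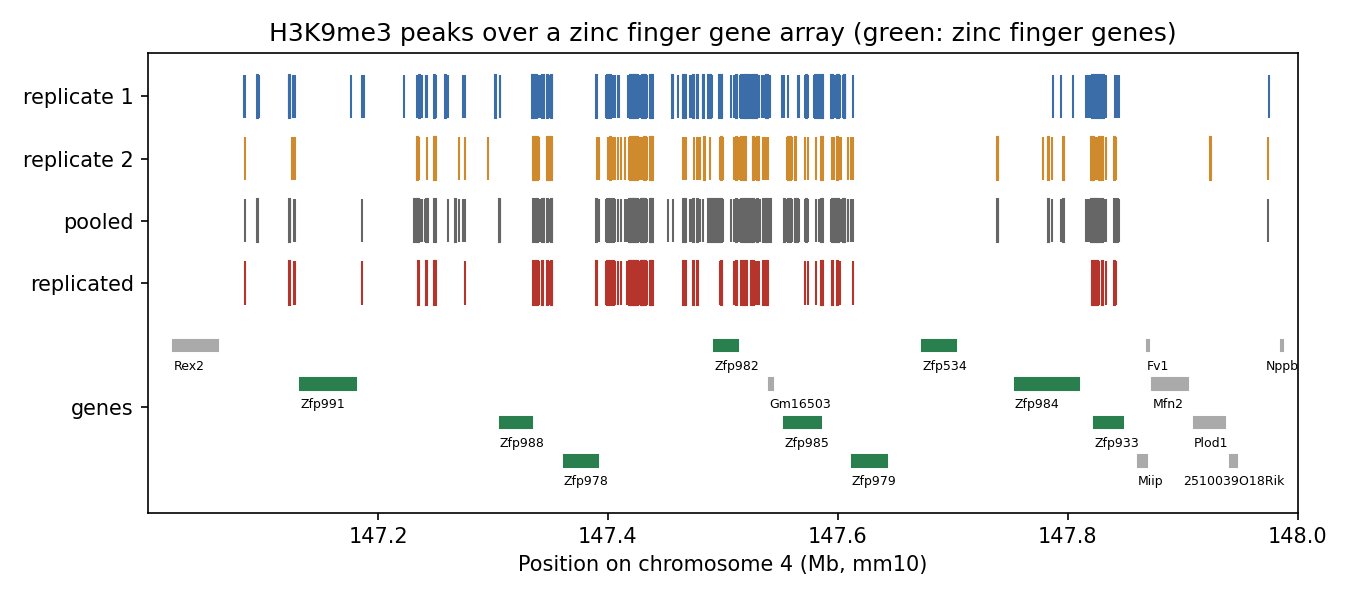
Peaks of the 4 lists along chromosome 4, 147000001 to 148000000 (horizontal axis, position in Mb, mm10), with protein-coding genes below and zinc finger genes in green. Each bar is 1 peak, drawn with a minimum line width, so the narrowest peaks look wider than they are; the window holds 193 replicate 1 peaks, 129 replicate 2 peaks, 195 pooled peaks and 95 replicated peaks, and many lie between annotated genes.

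Replicated peaks were unevenly spread over chromosomes. After merging peaks within 10 kb, 2868 domains remained. Chromosome 7 held 341 domains, 2.22-fold its share of ungapped sequence (95% exact interval 2.00 to 2.45, adjusted p = 1.29e-40 by exact binomial test), and chromosome 17 held 209, 2.10-fold its share (1.84 to 2.40, adjusted p = 5.02e-22, same test). Chromosomes 5, 4 and 13 were above their share by 1.25-fold, 1.23-fold and 1.23-fold. Chromosome X held 25 domains, 0.141-fold its share (0.0915 to 0.208, exact binomial adjusted p = 1.00e-46), and chromosome Y held 4, 0.0419-fold (0.0114 to 0.107). Their shares include masked sequence, which made up 46.8% of X and 96.3% of Y. Chromosomes 14, 15, 3 and 2 were also below their share, at 0.639-fold, 0.780-fold, 0.797-fold and 0.839-fold. Of the domains on chromosomes 7 and 17, 68.6% and 78.0% lay in the first 50 Mb. These 2 shares cannot be compared directly, since chromosome 7 is 145441459 bp long and chromosome 17 is 94987271 bp. The first 50 Mb is thus a larger part of chromosome 17. The binomial test treats domains as independent, so where domains cluster its intervals can be too narrow and its p-values too small. With merging within 50 kb, chromosome 7 stood at 1.56-fold, chromosome 17 at 1.71-fold and X at 0.154-fold, each still past the test. In the list of replicate 1 or replicate 2 alone, chromosomes 7 and 17 stayed above and X below their share, with folds nearer 1: 1.30 and 1.32 for chromosome 7 (1.40 in the pooled list), 1.39 and 1.46 for 17, and 0.493 and 0.386 for X (0.283 in the pooled list). The excess on chromosome 4 did not pass the test in the replicate 2 list (1.04-fold), with merging within 50 kb (1.09-fold) or in the pooled list (1.03-fold, exact binomial adjusted p = 0.328).

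**Figure D3:**
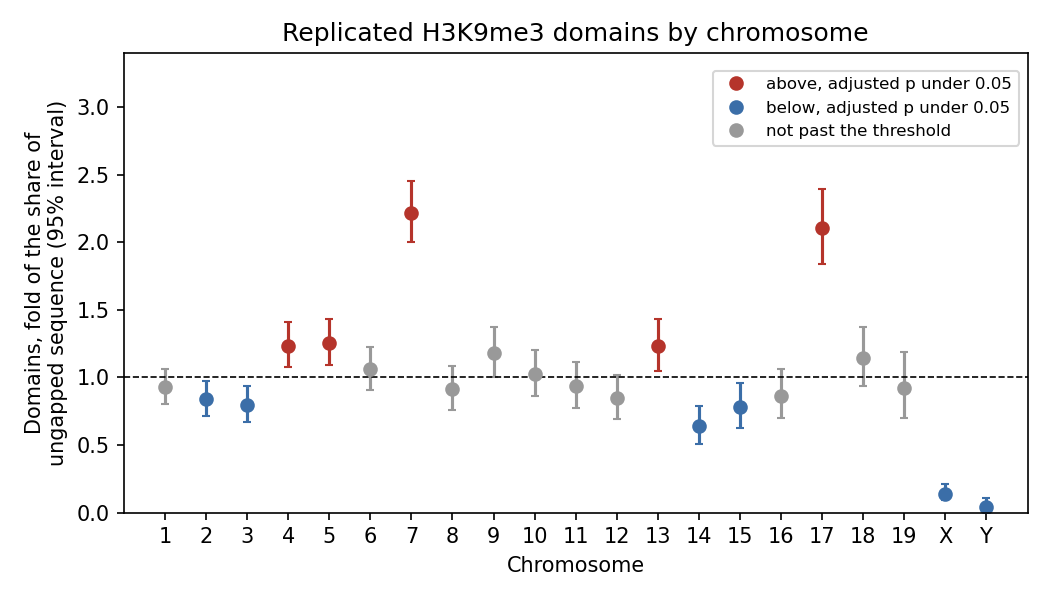
Replicated H3K9me3 domains per chromosome (horizontal axis) as a fold of the chromosome's share of ungapped sequence (vertical axis), with exact 95% binomial intervals, red where above and blue where below at an adjusted p under 0.05. Chromosomes 7 and 17 lie at 2.22 and 2.10, and X and Y at 0.141 and 0.0419. The intervals treat domains as independent and can be too narrow where domains cluster.

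Relative to genes, 2692 replicated peaks (62.0%) had their midpoint between protein-coding genes, 1141 (26.3%) in introns, 333 (7.67%) in exons and 173 (3.99%) within 1 kb of a TSS. Exons held more peaks than under rotation (mean 3.32%, permutation p = 0.0002) and introns fewer (35.9%, p = 0.0002). The intergenic share did not pass the test against rotation (58.0%, permutation p = 0.0704). It passed above rotation in the pooled list (69.0%) and the lists of replicates 1 and 2 (69.8% and 67.5%, permutation p = 0.002 for each). At a −log10 q of at least 5 it lay below rotation without passing (50.2%, permutation p = 0.0899). The promoter share was above rotation (2.72%, permutation p = 0.0016), but this direction held only for the replicated list and its subsets: it was 2.29% in the pooled list, 2.14% in the replicate 1 list and 2.13% in the replicate 2 list, each below its own rotations. The exon share was 3.80% in the pooled list, 3.69% in the replicate 2 list and 3.60% in the replicate 1 list, where it did not pass the test (permutation p = 0.0579). Masked sequence made up 29.6% of peak bases against 34.0% under rotation, and GC bases 45.8% against 42.1% (permutation p = 0.0002 for both).

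Of 21915 genes, 963 (4.39%) held a replicated peak, against a mean of 982 under rotation (permutation p = 0.604). Which side of rotation this count took depended on the list: it was 1.47-fold at a −log10 q of at least 5, but 0.826-fold in the pooled list and 0.795-fold and 0.811-fold in the lists of replicates 1 and 2 (permutation p = 0.002 for each). Zinc finger and imprinted genes were the exceptions among the fixed lists, as 3 of the 19 lists passed the test. The shares are plotted by list against their rotations.

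**Figure D4:**
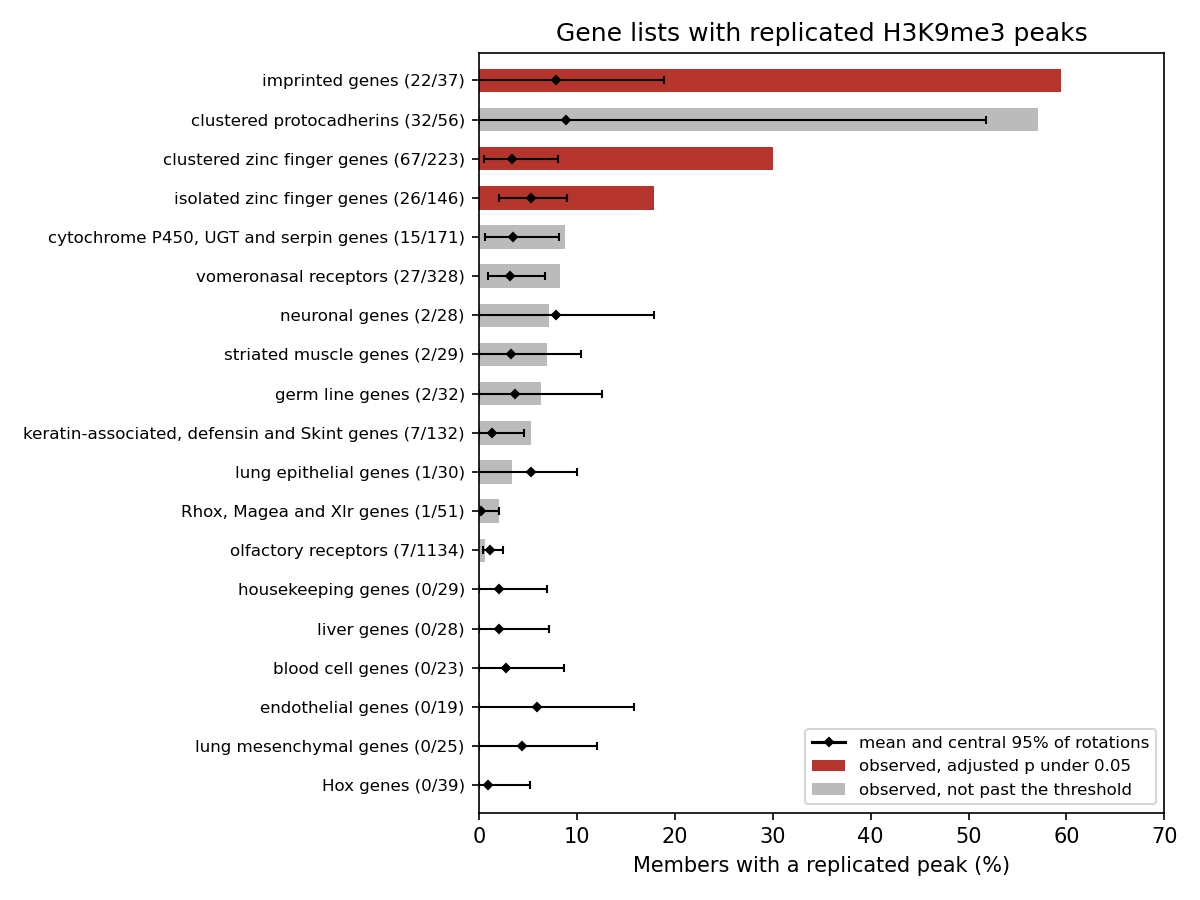
Members of each fixed gene list with a replicated peak, as a percentage (horizontal axis), with counts in brackets; bars are observed shares, red where the adjusted p is under 0.05, and diamonds with lines are the mean and central 95% of rotations. Imprinted genes (22 of 37) and clustered (67 of 223) and isolated (26 of 146) zinc finger genes lie above their rotations and pass the test.

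Clustered zinc finger genes held a replicated peak in 67 of 223 cases (30.0%), 8.90-fold over the rotation mean of 7.53 genes (95% of rotations 1 to 18, adjusted permutation p = 0.00127). They lay on 12 chromosomes, with 16 of 81 members on chromosome 7, 12 of 36 on chromosome 17, 9 of 13 on chromosome 9 and 8 of 15 on chromosome 4, but 0 of 10 on chromosome 5. Zfp981 (chromosome 4: 146502027 to 146539395) held 24 peaks over 13433 bp, 35.9% of its span. Zfp110 (chromosome 7: 12834761 to 12850577) held 12 peaks over 72.1% of its span, and Zfp873 on chromosome 10 held 10 peaks over 56.2%. Zfp180 on chromosome 7 held 5 peaks over 5879 bp, of which the one with the highest fold, 5.25, lay over an exon with untranslated sequence. Isolated zinc finger genes held a peak in 26 of 146 cases (17.8%), 3.35-fold over rotation (7.76 genes, 3 to 13, adjusted permutation p = 0.00127). Zfp930 on chromosome 8 held 14 peaks over 8300 bp, Zfp369 on chromosome 13 held 10 over 4726 bp, Zfp945 on chromosome 17 held 5 over 4046 bp, and Zfp37 on chromosome 4 held 5 over 3695 bp. The share of marked members was 12.2 percentage points higher for clustered than for isolated genes, against a mean of −1.94 under rotation (permutation p = 0.0002). The fold of the clustered list was 29.4 among peaks with −log10 q of at least 5, 4.90 within 1 kb of a TSS, 2.95 in the pooled list, and 2.62 and 2.97 in the lists of replicates 1 and 2. The isolated list lost its call in the pooled list (1.32-fold, adjusted permutation p = 0.0759) and in the replicate 2 list (1.27-fold, adjusted permutation p = 0.171).

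Imprinted genes, expressed from 1 parental allele, held a replicated peak in 22 of 37 cases (59.5%), 7.61-fold over the rotation mean of 2.89 genes (0 to 7, adjusted permutation p = 0.00127). Counting overlapping spans once, the 22 genes made up 19 loci on 9 chromosomes with 51 distinct peaks. Gnas, which encodes a G-protein subunit (chromosome 2: 174284320 to 174346744), held 8 peaks over 7009 bp. Mest on chromosome 6 held 3 peaks over 3332 bp, the one with the highest fold (4.96) over exonic sequence within 1 kb of a TSS (30737531 to 30738982). Grb10, an adaptor of growth factor receptors on chromosome 11, held 3 peaks over 2573 bp, the one with the highest fold (5.19) likewise within 1 kb of a TSS (12025278 to 12027194). That gene had 3 peaks recovered in replicate 1 but 1 in replicate 2. Airn, a non-coding RNA antisense to Igf2r on chromosome 17, held 5 peaks over 2981 bp. Within 1 kb of a TSS, 17 of the 37 genes had a replicated peak, against a mean of 0.347 under rotation. The list's fold was 18.0 among peaks with −log10 q of at least 5, 2.59 in the pooled list and 2.48 and 2.29 in the lists of replicates 1 and 2.

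Among genes with the peaks of highest fold, Klf14, a single Krüppel-like transcription factor gene (chromosome 6: 30956023 to 30959078), came first: 1 peak of 2746 bp at 8.48-fold covered 89.9% of the gene and was found in both replicate lists. Gm44973 on chromosome 7 followed with a 3256-bp peak at 7.26-fold, in an intron of that gene, then Gm42416, whose span crosses the protocadherin array on chromosome 18, at 7.10-fold. The rule takes 1 gene per peak, so any other gene whose span holds one of these peaks is not named, and its class is not counted. Of the 15 genes taken by this rule, 8 carry Zfp symbols: Zfp27 (6.42-fold), Zfp810 (6.41-fold), Zfp958, Zfp90, Zfp329, Zfp981, Zfp386 and Zfp68 (5.54-fold). For Zfp27, Zfp810, Zfp958, Zfp90, Zfp329 and Zfp386 the peak overlapped an exon with untranslated sequence. The remaining 4 were Habp4 (6.39-fold), AU041133 (6.08), 2610008E11Rik (5.57) and Ppp2r3d (5.57).

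Clustered protocadherins held a replicated peak in 32 of 56 cases, 6.49-fold over rotation, which did not pass adjustment (adjusted permutation p = 0.0861); all 56 lie in 1 region of chromosome 18, and 95% of rotations gave 0 to 29 genes. Their spans overlap, and the 32 genes made up 6 loci with 65 distinct peaks. The genes with the most bases under peaks were all of this array: Pcdhga1 held 56 peaks over 44386 bp (24.6% of its span), and Pcdhga2, Pcdhga3, Pcdhgb1, Pcdhga4, Pcdhgb2 and Pcdhga5 share most of these peaks, as do Gm42416, Gm37013 and Gm37388, whose spans cross the array. Within 1 kb of the TSS, extended by 5 kb or against genes matched on length, the list passed the test (adjusted permutation p = 0.0380, 0.0304 and 0.00759), as it did at 2.41-fold in the pooled list and 2.35-fold in the replicate 1 list. Matching on length does not keep the overlap of these spans. The list did not pass in the replicate 2 list (1.99-fold, adjusted permutation p = 0.0569). Nor did it at a −log10 q of at least 5 (19.3-fold, adjusted permutation p = 0.144) or without chromosomes X and Y (6.94-fold, adjusted permutation p = 0.0647).

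The other receptor and enzyme families did not pass adjustment with replicated peaks and whole gene spans, and 3 of these lists passed under some alternatives. Vomeronasal receptors, which detect pheromones, held a peak in 27 of 328 cases (2.65-fold, adjusted permutation p = 0.0598), among them Vmn2r102, Vmn2r60, Vmn2r98 and Vmn1r69. The call passed in the pooled and replicate 1 lists (1.87-fold and 1.88-fold, adjusted permutation p = 0.0285 and 0.00759), with spans extended by 5 kb, against genes matched on length and without chromosomes X and Y, whereas none of the peaks with −log10 q of at least 5 fell in these genes. In the replicate 2 list it did not pass (1.78-fold, adjusted permutation p = 0.0506). Keratin-associated, defensin and Skint genes held a peak in 7 of 132 cases (4.24-fold, adjusted permutation p = 0.0861), all 7 of them Skint genes, with 12 peaks in Skint6, 4 each in Skint5 and Skint4, and 3 in Skint2. That list passed against genes matched on length (3.24-fold, adjusted permutation p = 0.0217), a comparison that treats neighbouring Skint genes as independent. It did not pass in the pooled list (1.70-fold, adjusted permutation p = 0.270). Nor did it in the lists of replicates 1 and 2 (1.65-fold and 1.63-fold, adjusted permutation p = 0.228 and 0.232). Cytochrome P450, UGT and serpin genes held one in 15 of 171 cases (2.58-fold, adjusted permutation p = 0.100), in 7 loci, of which the Ugt1a genes share most of their peaks (9 in Ugt1a7c, and 8 in each of Ugt1a10, Ugt1a5 and Ugt1a6a). It passed at a −log10 q of at least 5 (9.64-fold, adjusted permutation p = 0.0380), with spans extended by 5 kb (p = 0.0316) and against genes matched on length (p = 0.0127), which does not keep the sharing of peaks. It did not pass in the pooled list (1.17-fold) or in the lists of replicates 1 and 2 (1.01-fold and 1.26-fold). Olfactory receptors, the largest list, held one in 7 of 1134 cases (0.550-fold, adjusted permutation p = 0.831), with Olfr1349, Olfr869, Olfr385 and Olfr348 holding 1 peak each. Their fold was on the other side of 1 in the pooled list (1.48) and in the lists of replicates 1 and 2 (1.55 and 1.53), where it did not pass the test either. Of 51 Rhox, Magea and Xlr genes, Rhox13 alone had a peak (adjusted permutation p = 0.376).

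No list of lung genes or of markers of other cell types passed the test with replicated peaks. Lung epithelial genes had 1 of 30 (adjusted permutation p = 1): 5 peaks fell in the annotated span of Fgfr2, the receptor for Fgf10, which extends over 2960900 bp in this annotation, and the peak with the highest fold there (3.21) was intronic and not found in the replicate 1 list. No member of the lung mesenchymal (25 genes), endothelial (19), blood (23), liver (28), housekeeping (29) or Hox (39) lists had one, against rotation means of 1.10, 1.13, 0.626, 0.549, 0.578 and 0.351 genes, so few that a count of 0 could not have passed below rotation, and depletion was not detectable with replicated peaks (adjusted permutation p from 0.962 to 1). The mesenchymal genes passed below rotation in the replicate 1 list alone (0.154-fold, adjusted permutation p = 0.0316), and not in the replicate 2 list (0.718-fold, p = 0.866) or the pooled list (0.893-fold, p = 1). Nkx2-1, the transcription factor of the lung lineage, Sftpc, which encodes surfactant protein C, and Tbx4, a mesenchymal transcription factor, had no peak in any of the 4 lists. Fgf10, a mesenchymal growth factor, had no replicated peak but 1 peak in each of the pooled, replicate 1 and replicate 2 lists. Among germ line genes, 2 of 32 had a peak (1.70-fold, adjusted permutation p = 0.962): Dazl, an RNA-binding protein of germ cells, with a peak at its TSS of 4.56-fold (chromosome 17: 50293332 to 50294088), and Meioc, a meiosis gene, with a peak of 2.78-fold inside the gene and within 1 kb of an annotated TSS. Neuronal genes had 2 of 28, Slc17a7 (4.04-fold, coding exon) and Syt1 (3.07-fold, intron), with an adjusted permutation p of 1. Striated muscle genes had 2 of 29, Ttn (3.59-fold) and Myh8 (3.38-fold), both over coding exons, with an adjusted permutation p of 0.921.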

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

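The tests of the most significant peaks were chosen after those peaks had been seen. The result below stood out because its peaks lie outside the assembled chromosomes used for every test.

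On unplaced or unlocalized scaffolds, 221 of the 4560 replicated peaks (4.85%) were found, spread over 19 scaffolds, of which 1 held 64. Of the peaks there, 62.4% of 335 in replicate 1 and 87.8% of 278 in replicate 2 were shared between the replicates. The difference from the assembled chromosomes (10.4% and 15.7%) was not tested. No rotations were run on scaffolds, so how much overlap densely placed peaks would give there by position alone is unknown. The shares therefore do not show better agreement between the replicates on scaffolds.

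Scaffolds also held 7 of the 25 replicated peaks with the smallest p, 6 lay over Sfi1 and Drg1 on chromosome 11, 2 at a ribosomal RNA sequence on chromosome 17 and 2 on chromosome 2 between 98663608 and 98667393 (mm10), over the predicted genes Gm10800 and Gm10801. A candidate explanation is that reads of many copies pile up on the 1 copy in the reference, which lowers p through depth without a high enrichment. The median fold of the 25 peaks was 2.82, below that of the replicated list (3.21), as this explanation needs. Of the 25, 8 had a fold above that median (3.23 to 6.08), and none of the 8 lay at the places named; whether the explanation holds for them was not tested. Real H3K9me3 on these repeats stays open, since the lists hold no reads and no biological explanation was tested.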

How the results depend on the processing

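Replicate overlap, intron share, masked and GC shares, the clustered zinc finger and imprinted lists, and the difference between clustered and isolated zinc finger genes kept their direction and their side of the threshold under every alternative run for them, as did the densities of chromosomes 7, 17 and X. In a further subset, the 97 domains with a −log10 q of at least 10, none of these 3 chromosomes passed (1.54-fold, 1.49-fold and 0.501-fold). The difference between clustered and isolated genes lay between 6.72 and 14.3 points. Read depth, which is not given, limits how many sites a list could hold. No paired analysis was possible because there is 1 group. One alternative, replicated peaks found in both replicate lists, was chosen after seeing the data. It put the neuronal list at 1.21-fold, on the other side of 1, and the number of chromosomes below their share at 4 instead of 6. No other gene list and no annotation share changed its call or direction under it.

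Under the alternatives set in advance, 180 values were the same, 19 passed the threshold that the reported value missed, 6 lost it, 8 moved without a test and 23 turned direction. The cause was not tested for any change listed here. Without a replicate means that the list of the other replicate, longer and with weaker peaks, was used. Coverage of 50% by both lists left 2138 replicated peaks. Chromosomes above their share numbered 3 at a −log10 q of at least 5 and 6 to 9 without a replicate. Those below numbered 3 at that q, 3 in the pooled list, 3 with merging within 50 kb, 10 with no merging and 3 to 4 without a replicate. The promoter share reversed to 2.29% in the pooled list and 2.13% to 2.14% without a replicate. The exon share was 3.60% to 3.69% without a replicate. The intergenic share reversed to 50.2% at a −log10 q of at least 5, and passed the test at 69.0% in the pooled list, 67.5% to 69.8% without a replicate and 62.0% against shuffled peaks.

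Gene list folds follow. In the pooled list they were 1.32 for isolated zinc finger genes, 1.48 for olfactory receptors, 1.87 for vomeronasal receptors, 2.41 for protocadherins, 0.937 for Rhox, Magea and Xlr genes, 1.12 for endothelial, 0.969 for striated muscle and 1.32 for housekeeping genes. Without a replicate they were 1.27 to 1.44 for isolated zinc finger genes, 1.53 to 1.55 for olfactory receptors, 1.78 to 1.88 for vomeronasal receptors, 1.99 to 2.35 for protocadherins, 0.479 to 1.48 for Rhox, Magea and Xlr genes, 0.154 to 0.718 for lung mesenchymal, 0.659 to 1.31 for neuronal and 0.772 to 1.06 for striated muscle genes. At a −log10 q of at least 5 they were 0 for vomeronasal receptors, 0 for Rhox, Magea and Xlr genes, 0 for striated muscle genes, 2.67 for neuronal genes and 9.64 for P450, UGT and serpin genes, the last past the threshold. With spans extended by 5 kb they were 1.48 for olfactory receptors, 2.47 for vomeronasal receptors, 7.40 for protocadherins and 2.70 for P450, UGT and serpin genes, the last 3 past the threshold. Within 1 kb of the TSS they were 0.752 for vomeronasal receptors, 72.7 for protocadherins and 0 for striated muscle genes. Against genes matched on length they were 3.42 for vomeronasal receptors, 7.74 for protocadherins, 3.24 for keratin-associated, defensin and Skint genes, 2.62 for P450, UGT and serpin genes, these 4 past the threshold, 1.04 for lung epithelial and 1.06 for neuronal genes. With chromosomes X and Y left out, vomeronasal receptors stood at 2.66.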

Other observations

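The tests of sharing between the replicates were chosen after the results had been seen; those of chromosomes, of positions within genes and of similar sequences were set before their results.

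Within zinc finger genes the mark lay toward the 3′ end. In the 108 zinc finger genes with a replicated peak, the mean position of peak bases along the gene, from 0 at the start to 1 at the 3′ end, was 0.757 ± 0.208 (SD over genes), and 94 of them (87.0%) had it past the middle (two-sided permutation p = 1e-05 by flipping genes, the smallest that 100000 flips can give). In the 852 other protein-coding genes with a peak it was 0.491 ± 0.281 (permutation p = 0.325). The difference of 0.266 also had the smallest p of its permutation, 1e-05, although neighbouring genes of an array are not independent. The last exon of such genes encodes the zinc fingers, and a candidate explanation is that the mark follows that exon. Reads shared between similar zinc finger exons were not tested and stay open.

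If H3K9me3 marked copies of a few repeated sequences, replicated peaks would resemble each other. A similar sequence (at least 80% identity over 150 bp) in another replicated peak more than 1 Mb away or on another chromosome was found for 518 of 4339 peaks (11.9%). This was fewer than in 20 shuffled sets, which gave a mean of 15.8% ± 0.497 (SD) and at most 17.2%. This does not exclude repeated copies, although a share below the highest shuffled set had been set beforehand to do so. The shuffled sets were not matched on masked sequence, of which the peaks held less than rotated ones (29.6% against 34.0%). Shuffling also placed each peak singly within its chromosome, which breaks up arrays. Similar peaks within 1 Mb were not counted, so similar neighbours could be left out more often for the real peaks. The treatment of multiply mapped reads, which is not given, may have removed such sites. Similar peaks formed 125 families, the largest of 68 peaks on 19 chromosomes.

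Few peaks were shared between the replicates. A permissive threshold in the peak calling is 1 candidate explanation: of peaks with a −log10 q of at least 5, 74.6% of 354 in replicate 1 (exact 95% interval 69.7 to 79.0) and 95.1% of 81 in replicate 2 had a match in the other full list, against 6.92% and 13.1% of those with a q above 0.05. The replicate 1 value fell short of the share set for it, so the threshold cannot be told apart from other causes by this test. Lower depth or enrichment in replicate 2, of whose peaks 8.79% reached a q of 0.05 against 30.9% in replicate 1, cannot be told apart either. With both lists cut to their 20838 most significant peaks, 77.4% of the 4339 replicated peaks overlapped replicate 1 and 77.6% replicate 2. The difference was −0.277 points (two-sided exact McNemar p = 0.792). The cut shortened only the replicate 1 list, since 20838 is the whole replicate 2 list on assembled chromosomes. Without it, 3973 replicated peaks overlapped replicate 1 and 3369 replicate 2. The replicated list was derived from both replicates, and lists of equal length can hide a difference in depth, so this test cannot decide. A difference between the pools stays open and was not tested.

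Chromosomes 7 and 17 had more than their share of domains, and X and Y few. Arrays of zinc finger genes, as defined by symbol, do not account for the pattern on chromosomes 7, 17 and X as a whole. Any zinc finger genes with other symbols were not left out. With sequence within 250 kb of the 425 zinc finger genes left out, chromosome 7 still had 2.02-fold its share (95% interval 1.79 to 2.27), chromosome 17 had 2.00-fold (1.71 to 2.31) and X had 0.151-fold (0.0967 to 0.224). The intervals in this paragraph treat domains as independent and can be too narrow where domains cluster. A lower dose of X in pools of both sexes may reduce the power to call peaks there: at a −log10 q of at least 5, X stood at 0.329-fold, and among the 97 domains with at least 10 it held 3, or 0.501-fold (0.104 to 1.42). That interval includes 1, as set beforehand for this explanation, but also the 0.141 of the whole list, which was weighed only after the result was seen, so the counts are too few and the dose cannot be told apart from other causes. Masked sequence made up 46.8% of X and 96.3% of Y, against 36.4% of the ungapped genome. How reads from it were treated is not stated, and its part in the low X and Y folds was not tested.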
